A study of Mus musculus with 80 samples.

How the data were processed

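Whole lungs of adult male mice from Taconic were studied after a single 6 h inhalation of styrene or air, per the labels' protocols. Lungs were taken on the morning after the exposure, and the mice were kept on a 12 h light and dark cycle. RNA was extracted with Trizol and the RNeasy Mini protocol and labelled with the Affymetrix GeneChip HT 3' IVT PLUS kit, per the labels' protocols. Per the labels, there were 4 strains (C57Bl/6 WT, CYP2F2 knockout, CYP2F1 humanized and CD-1), 4 doses (0, 10, 40 and 120 ppm) and 5 biological replicates in each of the 16 groups, 80 arrays in all. The deposited table holds log2 signal for 45037 probe sets, made with RMA and Partek per the submitters' processing notes. Versions and settings of RMA and Partek are not given in the sources used here, nor is whether the strains were processed together. Values ran from 1.88 to 13.9. The arrays of WT had a mean median of 4.57, those of KO 4.16 and those of CD-1 4.27. Array medians ran from 4.53 to 4.60 in WT, 4.09 to 4.20 in KO, 4.24 to 4.30 in CD-1 and 3.84 to 4.14 in TG, where TG 0 ppm replicate 4 had the lowest and the next array stood at 4.07.

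Of the probe sets, 28898 carried 1 gene symbol in the supplied annotation, 551 carried several and 15588 were not in it. Only those with 1 symbol were used for named genes, and names were checked against the RefSeq gene table (GRCm38.p6 assembly). For each of the 17097 genes the probe set with the highest mean over all arrays stood for the gene, and 7180 genes had more than 1. A gene was tested when its signal lay above the median of the whole table (4.28) in at least 5 of the 80 arrays, which left 11406 genes. Pearson correlations between arrays of a group ran from 0.978 to 0.997 (median 0.994), and no pair of arrays within a group was a duplicate. Pairs across groups were not checked for this. The number of arrays per group limits the precision: the median standard error of a 120 ppm change was 0.083 in WT, 0.089 in KO, 0.109 in TG and 0.107 in CD-1.

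Linear models with moderated variance were fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8 for reading). Each strain was fitted alone with a mean per dose (20 arrays, 16 residual degrees of freedom), and each dose was compared with 0 ppm. The trend over the rank of the dose used weights from -3 to 3 and is given as a slope per dose step. Differences in response to 120 ppm between 2 strains were fitted on 40 arrays (32 residual degrees of freedom), and the strains were compared in air on the 20 control arrays. P values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05. A stricter count also asked for a 1.5-fold change. Where strains were compared in air, the median difference over all genes was subtracted from the printed gene values, and the tests were made on the values before subtraction.

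The gene names in the text follow a rule fixed before the data were examined. Cyp2f2 was always named. For each 120 ppm and baseline contrast the rule took the 10 largest rises and 10 largest falls among genes that passed and whose 5 arrays all lay on the same side of the other group's mean, and 5 and 5 for the other contrasts (for a trend or a response difference without the condition on arrays). For each list described it took up to 4 members with the lowest p. Genes named beyond it were chosen after their values were seen: Cxcl10, Mx1, Oasl1 and Rsad2 in KO, Cxcl10 and Mx1 in TG, and Cyp1a1 in WT at 10 ppm.

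The 32 gene lists were written before the data were examined. There were 14 lists of cell type markers: club, ciliated, alveolar type 1, alveolar type 2, endothelial, fibroblast, cardiac muscle, macrophage, neutrophil, B cell, T and NK cell, thymocyte, erythroid and adipose tissue. The other 18 were mitosis, DNA replication, NRF2 and glutathione, AHR targets, CAR and PXR targets, styrene and xenobiotic metabolism, the Cyp2 cluster around Cyp2f2, p53 targets, unfolded protein response and ATF4, heat shock, inflammation, interferon response, circadian clock, glucocorticoid response, sterol synthesis, fatty acid synthesis, PPAR targets and fatty acid oxidation, and immediate early genes. Lists were tested with camera in limma against all other genes with a preset correlation of 0.01 between genes, adjusted over the 32 lists, and again with the correlation estimated from the data. Member genes were also adjusted over the list alone. Lists for squamous epithelium and skeletal muscle were added after the data had been seen and serve to describe arrays.

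The scripts were tested on simulated data with 200 changed genes and fixed seeds. For a log2 change of 0.5, 1 and 2 they recovered 77.6, 98.5 and 100% of the changed genes at WT 120 ppm and 68.7, 97.0 and 98.5% at CD-1 120 ppm. They recovered 67.2, 94.0 and 100% for the difference between WT and KO, 82.1, 98.5 and 100% for the WT trend and 70.2, 98.5 and 100% for KO against WT in air. The share of false calls was 5.13, 5.38, 3.83, 2.6 and 7.14% in that order. A shift of 0.5 in the interferon list was found at WT 120 ppm, in the difference between WT and KO and in KO against WT. It was not found at CD-1 120 ppm, and 1 unshifted list was called in KO against WT. The simulated genes varied independently of each other. These results therefore do not show how the tests behave where genes are correlated, as members of a list can be.

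The settings varied, as fixed before the data were examined, were 1 fit over all arrays, no filter on low genes, median centring of each array, quantile normalization of the 80 arrays, trended and robust variance, array weights, the mean of a gene's probe sets, a replicate block, a fold change minimum, an estimated correlation and leaving out each array in turn. Contrasts between exposed WT groups, a fit without 4 arrays that stood apart and the same-sign shares were added after the data had been seen. The intended comparison of further Cyp2f2 probe sets was not possible, as only 1 probe set reads the gene. The same replicate numbers recur across doses, and over 30 pairs per strain the mean correlation of arrays with the same number was -0.00118 in WT, 0.0506 in KO, 0.00819 in TG and 0.0111 in CD-1 (pairs from -0.521 to 0.453), so the numbers were not treated as pairs. Each split of the arrays was repeated with up to 100 relabellings. Probe sets with several symbols were not used here, and those without a symbol were used only in the closing section.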

Results

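Gene expression was measured on Affymetrix arrays in whole lungs of adult male mice after 1 inhalation exposure of 6 h to styrene, an aromatic solvent used to make plastics. The mice breathed 0 (air), 10, 40 or 120 ppm, and the lungs were taken on the morning after the exposure, per the labels' protocols. The mice came from 4 strains: C57Bl/6 wild type (WT), CYP2F2 knockout (KO), CYP2F1 humanized (TG) and CD-1, an outbred stock. CYP2F2 is a cytochrome P450 of mouse club cells, the secretory cells of the airway lining, and oxidizes styrene, and CYP2F1 is its human counterpart. Each of the 16 groups held 5 arrays, 80 in all, with 45037 probe sets of log2 signal, of which 11406 named genes were tested. The number of arrays per group limits the precision. Changes are given in log2 units with the standard error and n = 5 arrays per group. Every gene named by rank in a dose or strain contrast lay on 1 side of the other group's mean in all 5 arrays.

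The targeted gene was examined first. In air, the mean log2 level of Cyp2f2 was 13.23 ± 0.03 in WT, 13.02 ± 0.09 in CD-1, 11.68 ± 0.10 in KO and 11.66 ± 0.19 in TG (SD, n = 5 each). Over all doses, the 20 arrays of KO ranged from 11.51 to 11.89 and those of TG from 11.48 to 12.00. On these values, which hold the shift between strains, they lay below every array of WT (12.04 to 13.27) and of CD-1 (12.50 to 13.14). The gap to the lowest WT array, at 40 ppm, was smaller than the shift in array medians. Those averaged 4.57 in WT and 4.16 in KO, and were lower still in TG. The separation from the lowest WT arrays therefore does not hold apart from that shift. In air, Cyp2f2 was lower in KO and TG than in WT also relative to the median difference, as given below. In WT, Cyp2f2 fell by 0.42 ± 0.08 at 10 ppm (adjusted p = 0.0018), by 0.97 ± 0.08 at 40 ppm (1.16e-07) and by 0.63 ± 0.08 at 120 ppm (2.25e-05). Its changes at 120 ppm were -0.05 ± 0.08 in KO, 0.14 ± 0.11 in TG and -0.09 ± 0.10 in CD-1, with adjusted p values of 0.988, 0.616 and 1. A single probe set read the gene, and its place relative to the deleted part is not given in the sources used here. A probe outside the deleted part checks nothing, and a residual signal in KO and TG carries no statement about transcript.

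**Figure D1:**
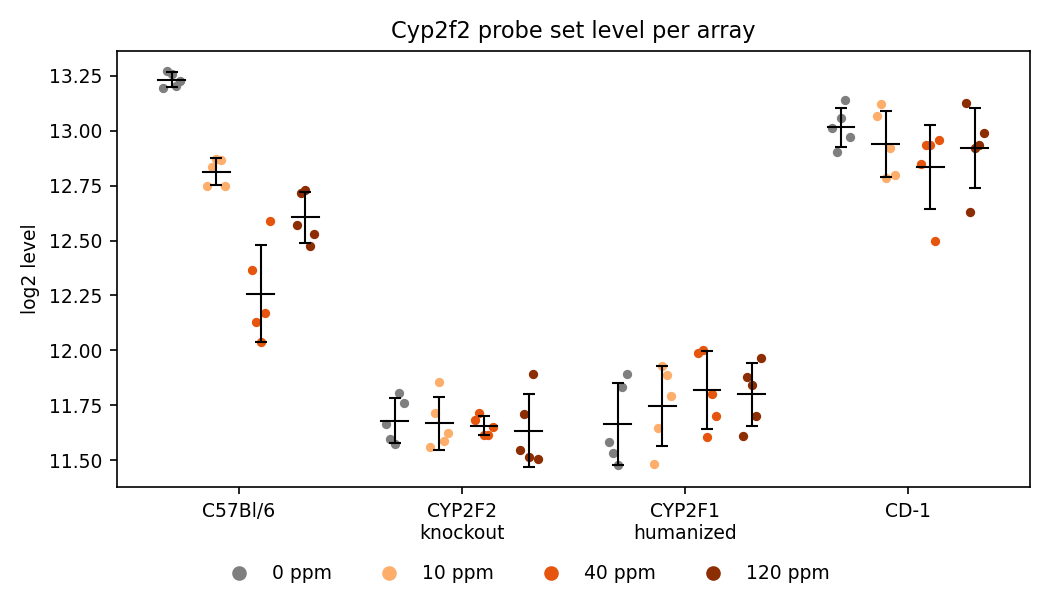
Log2 signal of the Cyp2f2 probe set in each of the 80 arrays, by strain and styrene dose in ppm, with 1 point per array and lines for the group mean ± SD (n = 5). The KO and TG arrays lie between 11.48 and 12.00, and the WT mean falls from 13.23 in air to 12.26 at 40 ppm.

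The comparison of 120 ppm with air in WT asked what the highest dose changed in the lung of a mouse with an intact Cyp2f2. Genes induced by interferon rose most. Cxcl10, a chemokine that draws T cells, rose by 4.89 ± 0.41 (29.6-fold, adjusted p = 1.17e-07). Mx1, an antiviral GTPase, rose by 4.02 ± 0.26 (5.4e-09), Oasl1, an antiviral regulator, by 4.00 ± 0.25 (4.88e-09) and Rsad2, the antiviral enzyme viperin, by 3.67 ± 0.26 (2.02e-08). Ifit1 rose by 3.07 ± 0.23, Ifit1bl1 by 2.78 ± 0.22 and Apol9a by 3.14 ± 0.27. Saa3, an acute phase protein, rose by 3.15 ± 0.40 and Timp1, an inhibitor of matrix proteases, by 2.88 ± 0.33. Gm9706, a predicted gene, rose by 3.75 ± 0.22. The largest fall was that of Cyp1a1, a P450 driven by the aryl hydrocarbon receptor, at -3.15 ± 0.40 (1.96e-05). The airway gene Lypd2 fell by 1.98 ± 0.38, the matrix protein gene Chad by 1.77 ± 0.38 and the transcription factor gene Mycl by 1.71 ± 0.18. Pon1, which encodes the esterase paraoxonase, fell by 1.69 ± 0.15 (1.73e-07) and the receptor gene Asgr1 by 1.61 ± 0.23. The bicarbonate transporter gene Slc4a5 fell by 1.44 ± 0.11, Npr3, a natriuretic peptide receptor, by 1.41 ± 0.20 and Fabp1, a fatty acid binding protein, by 1.39 ± 0.20. Sult1d1, a sulfotransferase, fell by 1.80 ± 0.62 (0.0394). Its call was lost on leaving out 1 of WT 0 ppm replicates 1, 2, 3 or 5 or WT 120 ppm replicates 1, 4 or 5 (adjusted p up to 0.111, values from -2.10 to -1.46). In all, 1629 genes rose and 1101 fell by limma, against 4142 at an unadjusted p under 0.05 where 570.3 were expected, and 328 and 160 of them changed at least 1.5-fold.

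Among the lists of genes fixed before the data were examined, 11 of 12 measured interferon response genes rose in WT at 120 ppm (list median 2.40, adjusted p = 1.4e-16). Ifit3 rose by 2.45 ± 0.20. The list's call was lost with an estimated correlation (adjusted p = 0.129 with an estimated correlation). DNA replication genes rose in 22 of 23 cases (median 0.75, adjusted p = 3.2e-18, and adjusted p = 0.0666 with an estimated correlation). Rrm2, a subunit of the enzyme that makes deoxynucleotides, rose by 1.40 ± 0.12, the polymerase gene Pole by 1.23 ± 0.12, the helicase gene Mcm3 by 0.84 ± 0.09 and the licensing factor gene Cdt1 by 0.84 ± 0.09. Of 16 mitosis genes, 7 rose and none fell (median 0.33, adjusted p = 0.0111, and adjusted p = 0.839 with an estimated correlation). The DNA topoisomerase gene Top2a rose by 1.09 ± 0.21, the mitotic kinase genes Cdk1 and Aurkb by 1.04 ± 0.23 and 0.58 ± 0.15 and the cyclin gene Ccna2 by 0.78 ± 0.21. Sterol synthesis genes rose in 14 of 16 cases (median 0.51, adjusted p = 8.57e-09, and adjusted p = 0.214 with an estimated correlation), and all 16 rose when adjusted over the list alone. Mvd rose by 0.86 ± 0.16, Cyp51 by 0.85 ± 0.14, Hmgcs1 by 0.66 ± 0.12 and Sqle by 0.65 ± 0.11, all enzymes on the path to cholesterol. Inflammation genes rose in 9 of 18 cases and fell in 1 (median 0.48, adjusted p = 0.000176, and adjusted p = 0.46 with an estimated correlation), and 11 rose and 1 fell when adjusted over the list alone. The monocyte chemokines Ccl7 and Ccl2 rose by 2.11 ± 0.25 and 1.98 ± 0.23, and the cytokine signalling inhibitor Socs3 by 1.41 ± 0.17.

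**Figure D2:**
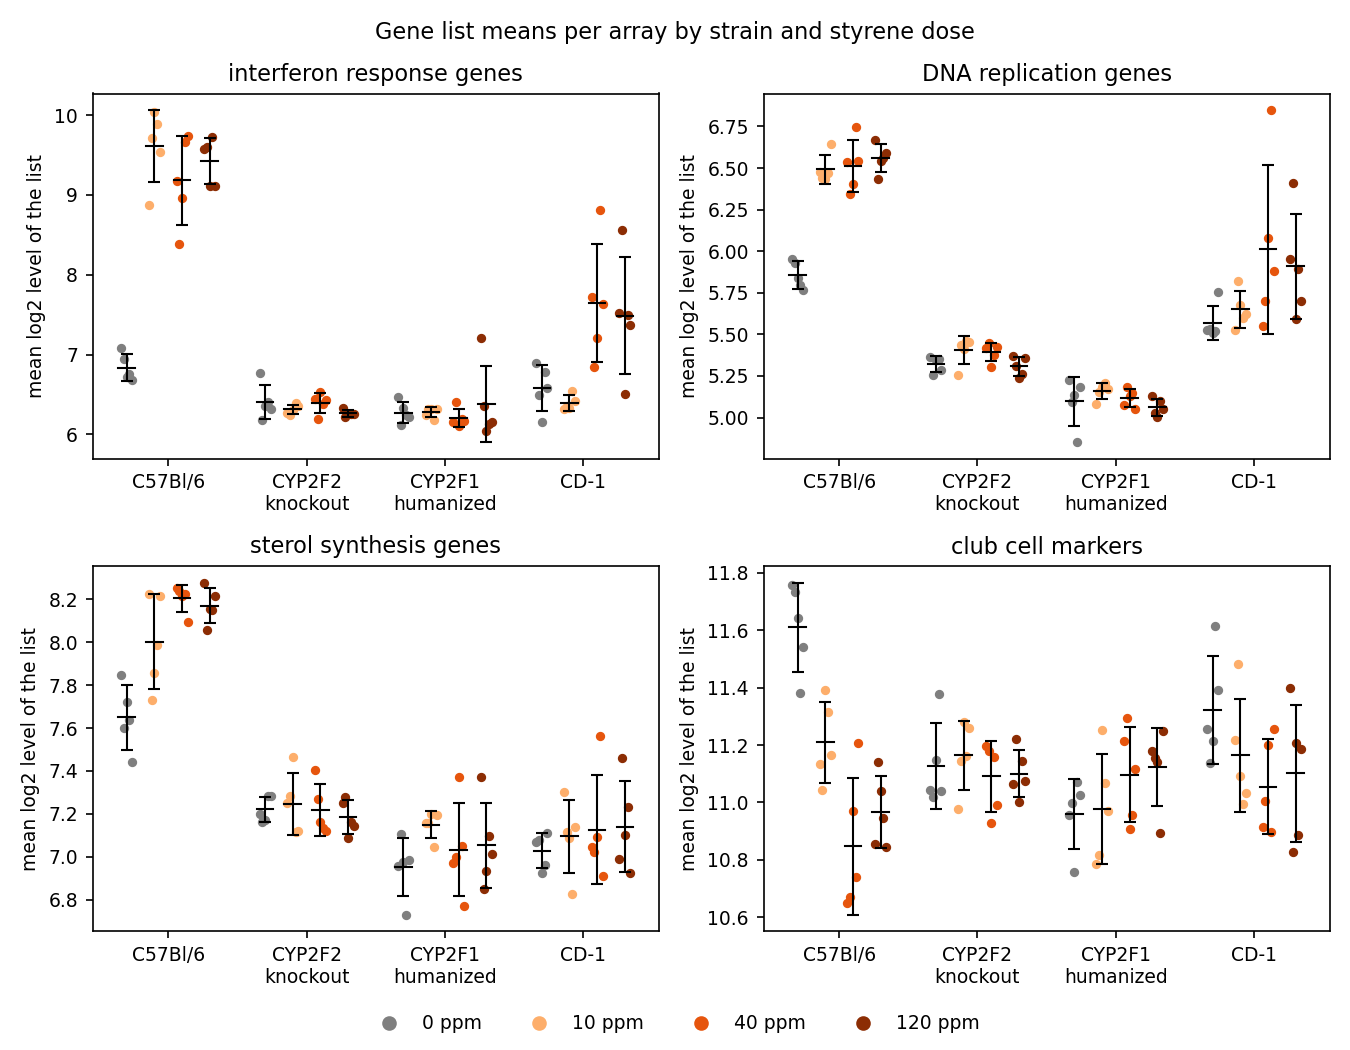
Mean log2 level of 4 gene lists (interferon response, DNA replication, sterol synthesis and club cell markers, 1 panel each) in each of the 80 arrays, by strain and styrene dose in ppm, with 1 point per array and lines for the group mean ± SD (n = 5). The interferon response mean of WT is 6.84 in air and 9.43 at 120 ppm, that of KO is 6.41 and 6.26, and that of CD-1 at 120 ppm is 7.49 with an SD of 0.73.

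Genes of oxidative defence rose in the same WT lungs, while genes of xenobiotic metabolism fell. In the NRF2 and glutathione list 12 of 23 genes rose and 3 fell (median 0.23, adjusted p = 0.0057, and adjusted p = 0.575 with an estimated correlation), 13 and 3 when adjusted over the list alone. Hmox1, which degrades heme, rose by 1.68 ± 0.20, the quinone reductase Nqo1 by 1.12 ± 0.11, Gclc, an enzyme of glutathione synthesis, by 0.56 ± 0.08 and Gsr, which recycles glutathione, by 0.55 ± 0.08. In the unfolded protein response and ATF4 list 8 of 18 rose and 1 fell (median 0.23, adjusted p = 0.00317, and adjusted p = 0.575 with an estimated correlation). The stress transcription factor genes Atf3 and Atf4 rose by 1.15 ± 0.17 and 0.42 ± 0.07, Trib3 by 0.64 ± 0.14 and the chaperone gene Hyou1 by 0.51 ± 0.12. Immediate early genes rose in 5 of 14 cases (median 0.27, adjusted p = 0.00317, and adjusted p = 0.46 with an estimated correlation), and 9 rose when adjusted over the list alone. Egr1 rose by 1.04 ± 0.27, Myc by 0.63 ± 0.13 and Ier3 by 0.56 ± 0.10. Of 25 styrene and xenobiotic metabolism genes 14 fell and 1 rose (median -0.35, adjusted p = 9.93e-08, and adjusted p = 0.182 with an estimated correlation). The aldehyde oxidase gene Aox3 fell by 1.17 ± 0.09, the carboxylesterase gene Ces1d by 0.69 ± 0.08 and the carbonyl reductase gene Cbr2 by 0.45 ± 0.06. Targets of the receptors CAR and PXR fell in 6 of 10 cases (median -0.32, adjusted p = 0.00116, and adjusted p = 0.152 with an estimated correlation). The aldehyde dehydrogenase genes Aldh1a7 and Aldh1a1 changed by -0.60 ± 0.07 and -0.43 ± 0.08, Alas1, the first enzyme of heme synthesis, by -0.41 ± 0.09 and the glutathione transferase gene Gstt1 by -0.40 ± 0.10.

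Of the 14 cell type marker lists, those of club and ciliated cells moved down in WT at 120 ppm. Club cell markers fell in 8 of 12 cases, Pon1 and Cyp2f2 among them (median -0.62, adjusted p = 1.01e-09, and adjusted p = 0.0666 with an estimated correlation), and in 9 when adjusted over the list alone. Ciliated cell markers fell in 3 of 12 cases (median -0.33, adjusted p = 0.000668, and adjusted p = 0.575 with an estimated correlation), namely Ccdc153 by 0.66 ± 0.16, Dnah5 by 0.62 ± 0.18 and Tppp3 by 0.46 ± 0.08. The other 12 cell type lists were not called. Their medians were 0.05 for alveolar type 2, 0.01 for alveolar type 1, 0.06 for endothelial, 0.01 for fibroblast, and -0.27 for cardiac muscle markers. For blood and immune cells they were 0.05 for macrophage, 0.10 for neutrophil, 0.34 for B cell, 0.09 for T and NK cell, 0.02 for thymocyte and 0.20 for erythroid markers, and the adipose tissue list stood at -0.45. The mean had the other sign than the median for macrophage (-0.04) and neutrophil (-0.01) markers. Single members passed: elastin (Eln) rose by 1.03 ± 0.18, fibronectin (Fn1) by 0.45 ± 0.12 and Col1a2 by 0.37 ± 0.11, while decorin (Dcn) fell by 0.77 ± 0.23. The surfactant protein gene Sftpd rose by 0.27 ± 0.06 and the water channel gene Aqp5 by 0.29 ± 0.07. Lists without a call also included AHR targets (median -0.15, 1 up and 1 down of 6), the Cyp2 cluster around Cyp2f2 (0.03, 1 up and 2 down of 9), p53 targets (0.05, 3 up and 1 down of 15), and heat shock genes (0.06, 1 up of 11). The same held for circadian clock (-0.28, 4 up and 7 down of 15), glucocorticoid response (0.17, 3 up of 15), fatty acid synthesis (-0.01, 1 up and 3 down of 12) and PPAR targets and fatty acid oxidation (-0.04, mean 0.05, 1 up and 1 down of 14). Within them, Hspa1b, an inducible heat shock protein, rose by 2.27 ± 0.43 (adjusted p = 0.00101), and Lcn2, an iron-binding acute phase protein, by 1.55 ± 0.20. Cdkn1a, the cell cycle inhibitor p21, rose by 0.67 ± 0.20 and Aen, a nuclease, by 0.57 ± 0.09.

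The lower doses asked whether the WT response was already present at 40 and 10 ppm. At 10 ppm Cxcl10 rose by 4.59 ± 0.41 (adjusted p = 2.18e-07), Oasl1 by 3.98 ± 0.25, Mx1 by 3.98 ± 0.26 and Rsad2 by 3.66 ± 0.26. The falls at 10 ppm were led by Pon1 (-1.40 ± 0.15), Fabp1 (-1.25 ± 0.20), the peroxisomal thiolase gene Acaa1b (-1.24 ± 0.21), Asgr1 (-1.19 ± 0.23) and Dcdc2a (-1.09 ± 0.10). At 40 ppm Cxcl10 rose by 4.23 ± 0.41 (7.01e-07), Oasl1 by 3.68 ± 0.25, Mx1 by 3.51 ± 0.26 and Saa3 by 3.46 ± 0.40. The falls at 40 ppm were led by Cyp1a1 (-3.43 ± 0.40), Lypd2 (-2.52 ± 0.38), Chad (-2.47 ± 0.38) and the airway secretion genes Bpifb1 (-2.30 ± 0.64) and Muc5b (-2.14 ± 0.56). Cyp1a1 differed from air by -0.84 ± 0.40 at 10 ppm (adjusted p = 0.18). Interferon response genes rose in 12 of 12 cases at 10 ppm (median 2.68) and in 11 of 12 at 40 ppm (2.33), and DNA replication genes in 20 of 23 (0.68) and 22 of 23 (0.66). At 10 ppm both lists kept their call with an estimated correlation (adjusted p = 0.047 each), and at 40 ppm neither did (adjusted p = 0.164 and adjusted p = 0.087 with an estimated correlation). Club cell markers fell in 6 of 12 cases at 10 ppm (median -0.29, adjusted p = 0.163 with an estimated correlation) and in 10 of 12 at 40 ppm (-0.72, adjusted p = 0.0785 with an estimated correlation). Sterol synthesis genes rose in 10 of 16 cases at 10 ppm (0.38, adjusted p = 0.335 with an estimated correlation) and in 13 of 16 at 40 ppm (0.52, adjusted p = 0.202 with an estimated correlation). By limma 875 genes rose and 559 fell at 10 ppm (3143 unadjusted), and 1559 rose and 1411 fell at 40 ppm (4365 unadjusted), of which 273 and 50, and 351 and 215, changed at least 1.5-fold. Without WT 10 ppm replicate 5 the count at 10 ppm was 919 in place of 1434.

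Direct contrasts between the exposed WT groups, added after the contrasts with air had been seen, asked whether the doses differed. From 10 to 120 ppm 71 genes rose and 32 fell, from 10 to 40 ppm 37 rose and 71 fell, and from 40 to 120 ppm limma called 0 (839 at an unadjusted p under 0.05, lowest adjusted p = 0.188). Between 40 and 120 ppm 3 lists were called up and 4 down, and none held with an estimated correlation. Club cell markers were lower at 120 than at 10 ppm in 3 of 12 cases (median -0.25, adjusted p = 1.62e-06, and adjusted p = 0.318 with an estimated correlation). None of the 12 interferon response genes passed between 10 and 120 ppm (median -0.19, adjusted p = 0.0498, and adjusted p = 0.783 with an estimated correlation). Over the rank of the dose, 1718 WT genes rose and 1244 fell. Slopes per dose step were 1.43 ± 0.13 for Cxcl10, 1.17 ± 0.08 for Oasl1, 1.16 ± 0.08 for Mx1 and 1.07 ± 0.08 for Rsad2. These slopes do not show a rise from dose to dose. Each of these genes stood about as far above air at 10 ppm as at 120 ppm, and every dose shared the same air arrays. Falling slopes were -1.20 ± 0.13 for Cyp1a1, -0.73 ± 0.12 for Lypd2, -0.69 ± 0.18 for the lipogenic gene Thrsp, -0.68 ± 0.12 for Chad and -0.24 ± 0.03 for Cyp2f2. Sult1d1 had a slope of -0.63 ± 0.19 (adjusted p = 0.0223), which did not pass without WT 120 ppm replicate 1 or 5 (adjusted p up to 0.0631).

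**Figure D3:**
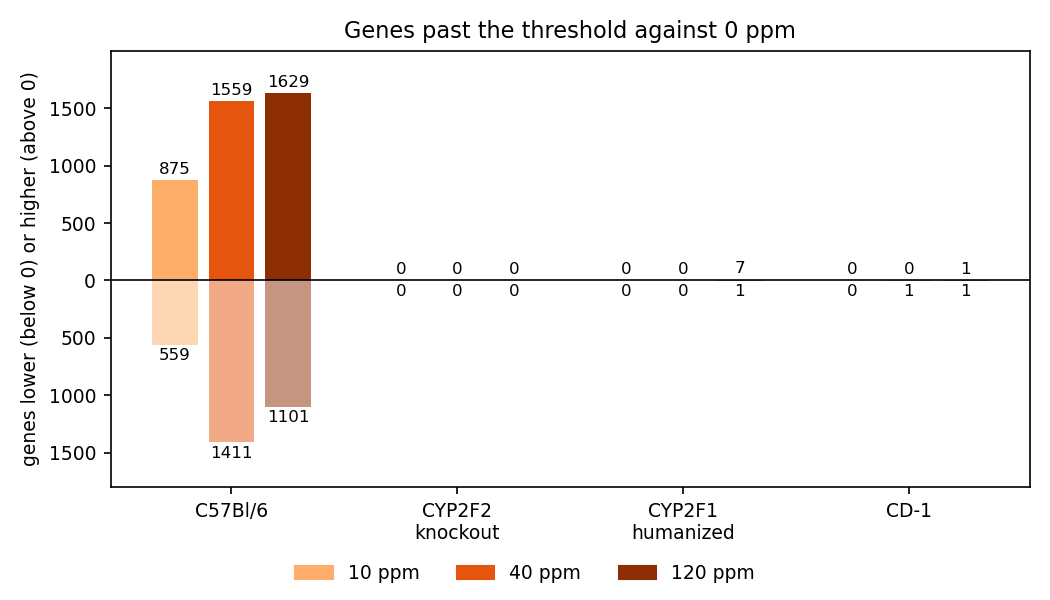
Number of genes with an adjusted p under 0.05 against 0 ppm, upwards for rises and downwards for falls, by strain and styrene dose in ppm (n = 5 arrays per group). WT has 1629 rises and 1101 falls at 120 ppm, where KO has 0, TG 7 and 1, and CD-1 1 and 1.

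In KO, whose Cyp2f2 is disrupted per the labels, the same contrasts asked what styrene changed in that strain. The genes that led the rise in WT stayed near their air level: Cxcl10 differed by 0.03, Mx1 by -0.03, Oasl1 by 0.04 and Rsad2 by -0.20 at 120 ppm. In KO air Cxcl10, Mx1 and Oasl1 averaged 3.71, 3.54 and 4.03, below the level minimum of 4.28. The interferon response list had a median of -0.16 with 0 of 12 genes passing (adjusted p = 0.0223, and adjusted p = 0.914 with an estimated correlation). Its call was lost without KO 0 ppm replicate 1 or KO 120 ppm replicate 4 (adjusted p up to 0.403). Glucocorticoid response genes had a median of -0.21 (adjusted p = 0.000118, and adjusted p = 0.914 with an estimated correlation), with 0 of 15 passing over all genes and 1 lower when adjusted over the list alone. Among its members, the lipase inhibitor gene Angptl4 stood at -0.56 ± 0.17, Pdk4 at -0.53 ± 0.20 and Fkbp5 at -0.50 ± 0.22. The same list had a median of -0.37 at 40 ppm (adjusted p = 6.4e-10, and adjusted p = 0.144 with an estimated correlation). Limma called 0 genes at 120, 40 and 10 ppm and in the trend, against 596, 564, 649 and 569 at an unadjusted p under 0.05 where 570.3 were expected, and the lowest adjusted p values were 0.252, 0.424, 0.0592 and 0.454. At 10 ppm 1 gene passed without KO 0 ppm replicate 4 and 2 passed without KO 10 ppm replicate 4. Of the 32 lists 2, 9 and 2 were called at 120, 40 and 10 ppm, and none held with an estimated correlation (lowest adjusted p = 0.144).

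In TG, humanized for CYP2F1 per the labels, few genes passed. Rgs5, a regulator of G protein signalling in pericytes, rose by 1.15 ± 0.16 at 120 ppm (adjusted p = 0.00594) and the chloride channel regulator Clca3a1 by 0.76 ± 0.11 (0.00868). Amigo2 rose by 0.65 ± 0.12 (0.0453), the sulfotransferase gene Sult1a1 by 0.64 ± 0.11 (0.0195), and Igfbp6 by 0.58 ± 0.10 (0.0367). The ubiquitin ligase gene Fbxo2 rose by 0.56 ± 0.11 (0.0453) and the lysosomal protease gene Ctsh by 0.36 ± 0.07 (0.0453), and the nuclear receptor gene Nr4a3 fell by 1.54 ± 0.25 (0.0195). Heat shock genes had a median of -0.31 (adjusted p = 4.9e-09, and adjusted p = 0.114 with an estimated correlation), with 0 of 11 passing over all genes and 5 lower when adjusted over the list alone. Hspa1b stood at -1.74 ± 0.46 (adjusted p = 0.13). In air Nr4a3, Hspa1b and the heat shock genes as a list stood higher in TG than in KO, as given below. A raised level in TG air was not separated from a fall after exposure, and it also enters the response difference of WT and TG. Xenobiotic metabolism genes had a median of 0.21 (adjusted p = 0.000209, and adjusted p = 0.147 with an estimated correlation), with 1 of 25 passing and 5 higher when adjusted over the list alone. Mitosis genes had a median of -0.24 with 0 of 16 passing and 2 lower when adjusted over the list alone (adjusted p = 1.72e-10, and adjusted p = 0.117 with an estimated correlation). The interferon response list was not called at 120 ppm, and Cxcl10 differed from air by -0.05 and Mx1 by -0.09. In TG air these 2 genes averaged 3.54 and 3.19, below the level minimum of 4.28, where a difference near 0 says little beyond the absence of a rise as in WT. Limma called 8 genes at 120 ppm and 0 at 40 and 10 ppm, against 1439, 867 and 1579 at an unadjusted p under 0.05 (lowest adjusted p at the lower doses 0.214 and 0.14). In the trend 7 genes rose and 1 fell, with slopes of 0.38 ± 0.05 for Rgs5, 0.26 ± 0.04 for Clca3a1, 0.23 ± 0.03 for Sult1a1, 0.21 ± 0.04 for Amigo2, 0.18 ± 0.03 for Igfbp6 and -0.49 ± 0.08 for Nr4a3. Of the 32 lists 12, 14 and 10 were called at 120, 40 and 10 ppm, and none held with an estimated correlation.

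Of the 8 TG calls at 120 ppm, 6 were lost on leaving out 1 array or another. The count at 120 ppm was 3 without TG 0 ppm replicate 1 or replicate 2 or TG 120 ppm replicate 1, 2 without TG 0 ppm replicate 3 or TG 120 ppm replicate 4. It was 4 without TG 120 ppm replicate 2, 5 without TG 0 ppm replicate 4 and 39 without TG 0 ppm replicate 5. Rgs5 and Clca3a1 kept their call without any array. Sult1a1 and Igfbp6 lost it without TG 0 ppm replicates 1, 2 or 3 or TG 120 ppm replicates 1, 2 or 4 (adjusted p up to 0.0838 and 0.101), and Nr4a3 without TG 0 ppm replicates 1, 2 or 3 or TG 120 ppm replicates 2 or 4 (up to 0.0838). Amigo2 lost it without TG 0 ppm replicates 2, 3 or 4 or TG 120 ppm replicates 1 to 4 (up to 0.132). Fbxo2 and Ctsh lost it without any of TG 0 ppm replicates 1 to 4 and of TG 120 ppm all but replicate 2 for Fbxo2 and replicate 3 for Ctsh (up to 0.136 and 0.138). At 40 ppm 1 gene passed without TG 0 ppm replicate 4 or TG 40 ppm replicate 2, and at 10 ppm 5 passed without TG 10 ppm replicate 1. The trend counted 28 genes without TG 0 ppm replicate 5, 4 without TG 40 ppm replicate 5 and 3 without TG 120 ppm replicate 4. The slope of Nr4a3 did not pass without TG 120 ppm replicate 4 (adjusted p = 0.0643). Those of Amigo2 and Igfbp6 did not pass without TG 40 ppm replicate 5, TG 120 ppm replicates 1, 2 or 4 or 3 further arrays for Amigo2 (TG 0 ppm replicates 3 and 4, TG 120 ppm replicate 3) and 2 for Igfbp6 (TG 0 ppm replicates 1 and 2), with adjusted p up to 0.0986 and 0.0878. With each array centred on its median, 2 genes rose and 1 fell at 120 ppm, and 1 fit over all 80 arrays called 119.

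CD-1, an outbred stock with Cyp2f2, asked whether the response extends beyond the inbred strain. At 120 ppm Stk36, a kinase gene of ciliated cells, rose by 1.55 ± 0.24 (adjusted p = 0.0186) and Acot1, a thioesterase of fatty acid metabolism, fell by 1.15 ± 0.16 (0.00942). At 40 ppm Pon1 fell by 1.46 ± 0.19 (0.00255). Interferon response genes had a median of 1.18 at 120 ppm (mean 0.91, adjusted p = 2.21e-09, and adjusted p = 0.264 with an estimated correlation), with 0 of 12 passing over all genes and 7 higher when adjusted over the list alone. Irf7 stood at 1.59 ± 0.39, Mx1 at 1.43 ± 0.38, Oasl2 at 1.38 ± 0.38 and Ifit3 at 1.11 ± 0.29. At 40 ppm the list's median was 1.15 with 0 passing and 7 higher when adjusted over the list alone (adjusted p = 1.73e-14, and adjusted p = 0.356 with an estimated correlation). At 10 ppm the interferon response list was not called (adjusted p = 0.11), with all 12 members lower by 0.03 to 0.57 and 0 passing, and neither was any other of the 32 lists. DNA replication genes had a median of 0.34 at 120 ppm (adjusted p = 8.46e-09, and adjusted p = 0.525 with an estimated correlation). At 40 ppm their median was 0.39 (adjusted p = 1.65e-15, and adjusted p = 0.374 with an estimated correlation). None of the 23 passed at either dose, and 1 and 5 were higher when adjusted over the list alone. PPAR targets had a median of -0.17 at 120 ppm (adjusted p = 6.59e-07, and adjusted p = 0.191 with an estimated correlation), with Acot1 passing and 3 lower when adjusted over the list alone, among them Acot2 at -0.98 ± 0.17. Circadian clock genes had a median of 0.68 (adjusted p = 0.000826, and adjusted p = 0.264 with an estimated correlation), with 8 higher and 2 lower when adjusted over the list alone. By limma the CD-1 counts were 2 at 120, 1 at 40 and 0 at 10 ppm, against 597, 442 and 272 at an unadjusted p under 0.05 (570.3 expected). The count at 120 ppm was 1 without CD-1 0 ppm replicate 2 or 3 or CD-1 120 ppm replicate 1 or 5, 4 without CD-1 120 ppm replicate 4, 5 without CD-1 0 ppm replicate 4 and 7 without CD-1 120 ppm replicate 3. Stk36 lost its call without 1 of CD-1 0 ppm replicates 1, 2 or 3 or CD-1 120 ppm replicates 1 or 5 (adjusted p up to 0.0721). In 1 fit over all 80 arrays 115 genes passed at 120 ppm and 44 at 40 ppm.

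The CD-1 trend called 4 rising and 3 falling genes. Slopes per dose step were 0.88 ± 0.16 for Gm9706, 0.69 ± 0.12 for Irf7, a transcription factor of the interferon system, 0.48 ± 0.08 for Stk36 and 0.30 ± 0.05 for Tspan4. They were -0.55 ± 0.10 for the clock gene Arntl, -0.37 ± 0.06 for Pon1 and -0.34 ± 0.05 for Acot1. Single arrays moved this count. It was 1 without CD-1 0 ppm replicate 2 or 5 or CD-1 120 ppm replicate 5, 2 without CD-1 0 ppm replicate 1 and 3 without CD-1 120 ppm replicate 2. It was 4 without CD-1 0 ppm replicate 3, CD-1 10 ppm replicate 3, 4 or 5, CD-1 40 ppm replicate 1 or 5 or CD-1 120 ppm replicate 4. It was 17 without CD-1 40 ppm replicate 2, 21 without CD-1 40 ppm replicate 4 and 22 without CD-1 120 ppm replicate 3. Gm9706 and Irf7 passed only without CD-1 40 ppm replicate 2, 3 or 4 or CD-1 120 ppm replicate 3 (adjusted p up to 0.147 each without 1 of the other 16). Arntl passed only without CD-1 0 ppm replicate 4, CD-1 10 ppm replicate 2, CD-1 40 ppm replicate 2 or 4 or CD-1 120 ppm replicate 1 (up to 0.133 without 1 of the other 15). Tspan4 was lost without CD-1 0 ppm replicate 1, 2 or 5 or CD-1 120 ppm replicate 4 or 5 (up to 0.114), and Pon1 without CD-1 0 ppm replicate 2 or 5 or CD-1 120 ppm replicate 2 or 5 (up to 0.0753). Stk36 was lost without CD-1 0 ppm replicate 1 or 2 or CD-1 120 ppm replicate 5 (up to 0.0753) and Acot1 without CD-1 0 ppm replicate 5 (0.055). In 1 fit over all 80 arrays the trend called 155 genes.

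Tests of the difference in response asked whether WT changed more than KO at 120 ppm. Cxcl10 rose more in WT by 4.86 ± 0.44 (adjusted p = 6.82e-10), Mx1 by 4.06 ± 0.27, Oasl1 by 3.96 ± 0.28 and Rsad2 by 3.86 ± 0.32, and Gm9706 by 3.90 ± 0.25. Differences in the other direction were largest for Cyp1a1 (-2.84 ± 0.47), Lypd2 (-2.13 ± 0.46), the clock output gene Dbp (-1.94 ± 0.48), Chad (-1.85 ± 0.45) and Fabp1 (-1.83 ± 0.26), and Cyp2f2 differed by -0.58 ± 0.11. Interferon response genes were higher in the WT response in 11 of 12 cases (median 2.40, adjusted p = 2.45e-28) and DNA replication genes in 17 of 23 (0.68), and club cell markers were lower in 7 of 12 (-0.54). These 3 lists held with an estimated correlation (adjusted p = 0.0046, 0.0046 and 0.0132). Gins2, a part of the replicative helicase, differed by 1.10 ± 0.13 and Scgb3a2, a club cell secretory protein, by -0.79 ± 0.13. Sterol synthesis (10 of 16 higher, median 0.55, adjusted p = 0.112 with an estimated correlation), and inflammation genes (8 of 18 higher, 0.40, adjusted p = 0.125 with an estimated correlation) were called with the preset correlation alone. So were xenobiotic metabolism genes (9 of 25 lower, -0.37, adjusted p = 0.0618 with an estimated correlation). In all, the change in WT exceeded that in KO for 804 genes and was below it for 501 (2982 unadjusted). This total of 1305 was 824 in 1 fit over all 80 arrays and 1998 with array weights.

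Between WT and TG, Cxcl10 differed in response by 4.93 ± 0.45 (adjusted p = 9.55e-10), Mx1 by 4.12 ± 0.31, Hspa1b by 4.01 ± 0.67 and Oasl1 by 3.92 ± 0.32, and Gm9706 by 3.59 ± 0.37. Lower in the WT response were Cyp1a1 (-3.99 ± 0.81), Thrsp (-2.86 ± 0.80), the mucin gene Muc16 (-2.22 ± 0.51), Chad (-2.16 ± 0.46) and Cyp2f2 (-0.76 ± 0.14). Sult1d1 differed by -2.66 ± 0.80, and its call was lost without TG 0 ppm replicate 3, WT 0 ppm replicate 2 or WT 120 ppm replicate 1 or 5 (adjusted p up to 0.0643). Of the 6 lists that held with an estimated correlation, those upwards were interferon response (11 of 12 higher, median 2.14, adjusted p = 0.00771 with an estimated correlation), DNA replication (18 of 23 higher, 0.72, 0.00268) and the unfolded protein response and ATF4 list (7 of 18 higher, 0.38, 0.041). Downwards they were club cell markers (7 of 12 lower, -0.72, 0.00805), CAR and PXR targets (7 of 10 lower, -0.42, 0.00805) and xenobiotic metabolism (14 of 25 lower, -0.51, 0.0108). Aox3 differed by -1.55 ± 0.12 and Gstm1, a glutathione transferase, by -0.66 ± 0.09. Counts were 441 up and 671 down. With each array centred on its median they were 705 and 470, and after quantile normalization of the 80 arrays 680 and 562, and array weights called 1706 in all. TG and KO did not differ in response for any gene by limma (1190 unadjusted, lowest adjusted p = 0.0698), with Cyp2f2 at 0.18 ± 0.13. Of the 32 lists 4 were called up and 9 down, and none held with an estimated correlation. The count of genes was 5 without KO 0 ppm replicate 1, 1 without KO 0 ppm replicate 5 or TG 0 ppm replicate 2, 3 without KO 120 ppm replicate 5 and 12 without TG 0 ppm replicate 5.

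Between CD-1 and WT the question was whether CD-1 responded less. The CD-1 response was lower for Cxcl10 (-3.63 ± 0.81, adjusted p = 0.00819), Saa3 (-3.12 ± 0.64), Rsad2 (-3.10 ± 0.48), Adm, a vasodilator peptide (-2.81 ± 0.40), and Oasl1 (-2.64 ± 0.49). It was higher for Cyp1a1 (3.75 ± 0.71), the clock output genes Dbp (3.42 ± 0.73) and Hlf (2.04 ± 0.36), the clock gene Per3 (2.01 ± 0.38), Stk36 (1.93 ± 0.28) and Cyp2f2 (0.53 ± 0.13). Interferon response genes were lower in 5 of 12 cases (median -1.35, adjusted p = 7.03e-10, and adjusted p = 0.155 with an estimated correlation), and in 10 when adjusted over the list alone. Inflammation genes were lower in 7 of 18 cases (-0.41, adjusted p = 3.53e-06, and adjusted p = 0.155 with an estimated correlation), with Socs3 at -1.54 ± 0.21 and Ccl2 at -1.80 ± 0.33. Club cell markers were higher in 5 of 12 cases (0.47, adjusted p = 4.88e-08, and adjusted p = 0.155 with an estimated correlation). Xenobiotic metabolism genes were higher in 8 of 25 (0.45, adjusted p = 8.33e-08, and adjusted p = 0.155 with an estimated correlation). DNA replication genes passed in 0 of 23 cases (median -0.31, adjusted p = 0.00127, and adjusted p = 0.591 with an estimated correlation). Counts were 191 up and 307 down, 498 in all, 913 with array weights and 326 without CD-1 120 ppm replicate 3.

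The strains were also compared in air, to describe what differed before exposure. Strain was not randomised, so these contrasts hold any difference between the colonies and arrays and are not effects of the Cyp2f2 genotype alone. Most genes that passed were lower than in WT: 8506 of 8552 in KO, 9082 of 9167 in TG and 5546 of 6090 in CD-1. The median difference over all genes was -0.36 for KO, -0.48 for TG and -0.23 for CD-1, and each difference below is given relative to that median. After quantile normalization of the 80 arrays 848 genes were higher and 723 lower in KO, 2189 and 1902 in TG and 2084 and 1722 in CD-1. Relative to the median, KO exceeded WT most in Npr1, a natriuretic peptide receptor (3.11 ± 0.10, adjusted p = 3.35e-13), Lrmda (2.29 ± 0.12), Cd1d2 (1.73 ± 0.09) and the proton pump gene Atp6v1b1 (1.47 ± 0.24). Next came the B cell genes H2-Ob (1.35 ± 0.30), Ms4a1 (1.31 ± 0.28) and Spib (1.21 ± 0.26), Mirt1 (1.26 ± 0.14), the chemokine receptor gene Ccr6 (1.26 ± 0.19) and Cfl2 (1.20 ± 0.15). It was lowest in Pttg1, the securin gene (-3.74 ± 0.47), the carboxylesterase gene Ces1f (-2.40 ± 0.16), Fetub (-1.69 ± 0.33), the mucus protein disulfide isomerase gene Agr2 (-1.49 ± 0.49) and the glutathione peroxidase gene Gpx2 (-1.46 ± 0.17). Cyp2f2 was lower by -1.19 ± 0.08. B cell markers passed upwards in 2 of 7 cases (adjusted p = 1.75e-12, and adjusted p = 0.0596 with an estimated correlation). Before subtraction NRF2 and glutathione genes passed downwards in 21 of 23 cases, where 8506 of all 11406 genes did (list median -0.51, adjusted p = 0.00978, and adjusted p = 0.42 with an estimated correlation). After quantile normalization the median of the NRF2 and glutathione list in KO minus WT at 0 ppm was -0.14 (adjusted p = 0.00667). The genes of cornified epithelium Rptn (-2.30), Sprr2a1 (-1.85), Psapl1 (-1.67) and Lce3b (-1.66) were also lower in KO. Their calls were lost without WT 0 ppm replicate 1 (adjusted p of 0.108, 0.113, 0.0968 and 0.0691). The squamous epithelium mean of that array was 10.05 against 4.43 to 4.80 in the other WT controls. Rptn also lost its call without KO 0 ppm replicate 3 or 5, and Sprr2a1 without KO 0 ppm replicate 1, 2, 3 or 4.

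TG exceeded WT in air most in the phosphodiesterase gene Gdpd3 (3.48 ± 0.88 relative to the median, adjusted p = 0.00423), Lrmda (2.24 ± 0.12), Hpcal4 (2.04 ± 0.33), and Fank1 (1.44 ± 0.13), followed by Spen (1.24 ± 0.09), Kdm4b (1.13 ± 0.14), Cbfa2t3 (1.12 ± 0.09), Nav1 (1.10 ± 0.12) and Plekho1 (1.07 ± 0.13). Hspa1b was higher by 1.98 ± 0.63, a call lost without TG 0 ppm replicate 1, 2 or 3 or WT 0 ppm replicate 4 or 5 (adjusted p up to 0.103). TG was lowest in Ces1f (-2.32 ± 0.16), Tceanc2 (-1.99 ± 0.09), the urothelial and mesothelial gene Upk3b (-1.60 ± 0.40), Fetub (-1.58 ± 0.33), Gpx2 (-1.45 ± 0.17), Muc16 (-1.45 ± 0.40) and Mia (-1.38 ± 0.16). Cyp2a5, a neighbour of Cyp2f2, followed at -1.38 ± 0.63, with an SD of 1.27 over the TG air arrays. Its call was made before subtraction, on a value that holds the shift of the whole strain. Cyp2f2 was lower by -1.09 ± 0.08. Sprr2a1 (-1.87) and Psapl1 (-1.53) were lower as well, again not without WT 0 ppm replicate 1 (adjusted p of 0.0739 and 0.102). Between TG and KO the median difference was -0.10 (2593 of 3270 genes lower in TG, 1545 up and 1546 down after quantile normalization). Relative to it TG was higher in Gdpd3 (3.89 ± 0.88), Hspa1b (2.83 ± 0.63), Pttg1 (2.83 ± 0.47), the chaperone gene Hsph1 (1.64 ± 0.34), Nr4a3 (1.51 ± 0.26), Ahsa2 (1.25 ± 0.28), Spen (1.11 ± 0.09) and Gnao1 (1.07 ± 0.20). It was lower in Npr1 (-2.11 ± 0.10), Tceanc2 (-1.96 ± 0.09), the cytotoxic cell gene Nkg7 (-1.73 ± 0.33), and the cold-inducible gene Cirbp (-1.59 ± 0.23). Smaller differences were those of Cd1d2 (-1.41 ± 0.09), Asgr1 (-1.35 ± 0.31), Ifitm6 (-1.22 ± 0.21), Mirt1 (-1.21 ± 0.14) and Bank1 (-1.20 ± 0.27). Erdr1 (1.63 ± 0.47) was not called without KO 0 ppm replicate 3 or 5 or TG 0 ppm replicate 5 (adjusted p up to 0.0584), nor the immunoglobulin gene Iglv1 (-1.45 ± 0.47) without TG 0 ppm replicate 3 (0.0506). Heat shock genes were higher in TG than in KO in 9 of 11 cases (median 0.54 before subtraction, adjusted p = 1.36e-06, and adjusted p = 0.54 with an estimated correlation). Cyp2f2 differed by -0.02 ± 0.08 before subtraction.

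CD-1 exceeded WT in air most in Tmem87a (4.62 ± 0.08 relative to the median, adjusted p = 8.78e-19), the protease inhibitor gene Serpina1b (4.58 ± 0.13), Ang5 (4.37 ± 0.53), and Fbp2 (4.32 ± 0.23). The MHC class II gene H2-Ea differed by 3.88 ± 0.67 before subtraction. Next came the WNT inhibitor gene Wif1 (3.72 ± 0.53), H2bc18 (3.58 ± 0.17), Ifi202b (3.46 ± 0.30), Rad51ap1 (3.29 ± 0.13) and Ctse (3.14 ± 0.34). It was lowest in Nxpe4 (-5.19 ± 0.12), Rbbp9 (-4.04 ± 0.12), Trim12a (-4.03 ± 0.10), and Smim6 (-3.99 ± 0.10). They were followed by the peptide transporter gene Slc15a2 (-3.70 ± 0.39), the interferon-inducible genes Ifi213 (-3.63 ± 0.12) and Ifi209 (-3.52 ± 0.11), Ankrd63 (-3.30 ± 0.19), Trim16 (-3.25 ± 0.36) and Prmt8 (-3.18 ± 0.16). Before subtraction, where 5546 of all 11406 genes passed downwards, ciliated cell markers did in 10 of 12 cases (median -0.77, adjusted p = 0.025, and adjusted p = 0.852 with an estimated correlation). That call was lost without CD-1 0 ppm replicate 3 (adjusted p = 0.0764). Sterol synthesis genes passed downwards in 14 of 16 cases (-0.64, adjusted p = 0.00678, and adjusted p = 0.719 with an estimated correlation). T and NK cell markers were higher in 6 of 11 and lower in 1 (0.60, adjusted p = 9.15e-07, and adjusted p = 0.522 with an estimated correlation). Cyp2f2 differed by 0.01 ± 0.08 relative to the median. Since the list test compares a list with all other genes, its direction was up for lists with a negative median in KO (endothelial, cardiac muscle, neutrophil, thymocyte, erythroid, adipose tissue and immediate early) and in TG (endothelial, fibroblast, B cell, adipose tissue, circadian clock and glucocorticoid response). In KO the T and NK cell list, also tested up, had a median of 0.03 and a mean of -0.01.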

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

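The test for influx of macrophages, neutrophils, B cells or T and NK cells and the lists for squamous epithelium and skeletal muscle were chosen only after the result was seen. Within each group of 5 arrays, an array was singled out when its gap to the nearest other exceeded 0.71 of the group's range, which chance does in about 1 in 20 groups. Over 8 measures in 16 groups this singled out 20 values, from 16 arrays, in 128 tests, where 6.4 were expected. The squamous epithelium and skeletal muscle lists are among the 8 measures and were added after the data had been seen. The 20 can therefore not be set against 6.4 as a test of chance.

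The largest gaps were in markers of tissue other than lung. The squamous epithelium mean was 10.05 in WT 0 ppm replicate 1 (others 4.43 to 4.80), 10.09 in WT 40 ppm replicate 3 (4.64 to 5.16), 8.62 in CD-1 0 ppm replicate 4 (3.77 to 4.07) and 5.54 in WT 120 ppm replicate 4 (4.64 to 4.87). The skeletal muscle mean was 7.42 in WT 0 ppm replicate 1 (3.82 to 4.24), 9.80 in WT 40 ppm replicate 3 (3.86 to 4.13), 9.89 in CD-1 0 ppm replicate 4 (3.45 to 3.64) and 6.43 in KO 0 ppm replicate 4 (3.54 to 3.85). Interferon response genes averaged 7.20 in TG 120 ppm replicate 1 (6.05 to 6.35). DNA replication genes averaged 6.65 in WT 10 ppm replicate 5 (6.43 to 6.47), 5.75 in CD-1 0 ppm replicate 5 (5.51 to 5.53) and 5.26 in KO 10 ppm replicate 1 (5.41 to 5.46). Sterol synthesis genes averaged 7.56 in CD-1 40 ppm replicate 4 (6.91 to 7.09), 7.04 in TG 10 ppm replicate 4 (7.16 to 7.20) and 8.10 in WT 40 ppm replicate 5 (8.21 to 8.26). Cyp2f2 stood at 12.50 in CD-1 40 ppm replicate 4 (12.85 to 12.96). Array medians were 3.84 in TG 0 ppm replicate 4 (4.07 to 4.13), 4.07 in TG 10 ppm replicate 1 (4.11 to 4.13), 4.09 in KO 120 ppm replicate 2 (4.17 to 4.18) and 4.53 in WT 120 ppm replicate 1 (4.58 to 4.59).

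Responses to 120 ppm differed between groups by a test of the difference for 1305 genes between WT and KO, 1112 between WT and TG and 498 between CD-1 and WT. Among 6760 probe sets without a gene name, which no comparison of the report used, 1026 changed in WT at 120 ppm (512 up and 514 down), and none did in KO, TG or CD-1 at that dose (449, 737 and 285 at an unadjusted p under 0.05).

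The first pattern weighed is the WT response, which technical causes might have produced. Scaling of the arrays is excluded as its whole cause, since 2696 genes passed at 120 ppm after quantile normalization against 2730 before. Influx of macrophages, neutrophils, B cells or T and NK cells stays open for the interferon genes. The highest of these 4 marker medians was 0.339 (B cell) while 11 of 12 interferon genes rose by over 1, but in 3 of the 4 lists the members went both ways, and markers with a high level in air would hide a small number of activated cells. Markers of monocytes and dendritic cells were not analysed here, and their influx stays open too. A cause confined to the WT arrays stays open. Of the genes called in WT at 120 ppm, 60% (1638) moved the same way in CD-1. That share was reached by 28 of 252 relabellings (exact p = 0.111, adjusted 0.5, highest other 67.2%). Over the genes called in WT at 40 ppm it was 70.8% in CD-1 (exact p = 0.0198, adjusted 0.178 over 9 tests), and at 10 ppm 55.3%. At 10, 40 and 120 ppm the shares were 39.0, 45.7 and 46.5% in KO and 56.6, 52.1 and 55.5% in TG. Metabolism of styrene by CYP2F2 is a biological explanation the design offers, and it stays untested apart from the strain.

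The second pattern is the small TG response. TG 0 ppm replicate 4, the array with the lowest median, could have set the count. Without it 5 genes passed at 120 ppm, inside the range that leaving out other arrays gave (2 to 39). So wide a range could hardly implicate any array, so the test decides little and this explanation stays open. The third pattern is that most strain differences in air pointed down. Of the genes that passed, 99.5% were lower in KO than in WT, and 46.0% after quantile normalization. That step gives all arrays the same median, so the even balance follows from it and decides nothing. Separate scaling of the strains and a true difference in total signal cannot be told apart here, since either would shift a whole strain and the normalization would remove both.

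Other splits of the same arrays, up to 100 for each comparison with the real one included, asked whether chance could have produced the counts. Chance is excluded for WT, where 1 of 100 splits, the real one, reached 2730 genes at 120 ppm (highest other 3), 2970 at 40 ppm (149), 1434 at 10 ppm (168) and 2962 in the trend (1635). The WT dose contrasts share the same air arrays, so they are not separate tests. Chance is excluded likewise, with 1 split each, for the differences in response between WT and KO (1305, highest other 452), WT and TG (1112, 82) and CD-1 and WT (498, 1). For the strain differences in air the real split also led, for KO and WT (8552, 8), TG and WT (9167, 4413), TG and KO (3270, 213) and CD-1 and WT (6090, 48). A shift of a whole strain would be enough for that. These splits in air therefore do not separate scaling of the strains from differences of single genes. For the CD-1 trend 1 split, the real one, reached 7 genes (highest other 1). That is the lowest share 100 splits can give, as for WT. In the CD-1 trend, however, only 2 of the other splits called any gene, and leaving out single arrays gave 1 to 22 genes, so chance is not excluded there. For TG at 120 ppm (8, highest other 9) and in the trend (8, highest other 105) and for CD-1 at 120 ppm (2, highest other 11) 2 splits reached the real count, and for CD-1 at 40 ppm 3 did (1, highest other 1). These shares lie under 0.05. For CD-1, however, only 3 of the other splits at 120 ppm and 2 at 40 ppm called any gene. Any real count above 0 would have given such a share, so it decides nothing for CD-1. A split that called 105 genes in the TG trend or 11 in CD-1, several times the real count, points to a structure of the samples, of which no cause was tested and from which an extreme relabelling was not separated. Where the real count was 0, all 100 splits reach it by construction, so the splits say nothing about chance there: KO 120 ppm (highest other 10), 40 ppm (1), 10 ppm (559) and trend (1), TG 40 ppm (1) and 10 ppm (29), CD-1 10 ppm (1) and TG against KO in response (1). In KO 10 ppm 5 and in TG 10 ppm 6 of the splits called any gene. The 559 and 29 could point to a structure of the samples too, again without a tested cause and not separated from an extreme relabelling.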

How the results depend on the processing

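The fit without the 4 arrays that stood apart (WT 0 ppm replicate 1, WT 40 ppm replicate 3, CD-1 0 ppm replicate 4 and TG 0 ppm replicate 4) was chosen only after the data were seen. Of 236 counts under other settings than leaving out 1 array, 186 stayed within 1.5 times their main value, and the cause was not tested for the others except where named. A 1.5-fold minimum, which by construction calls fewer genes, gave 488 for WT 120 ppm, 566 for WT 40 ppm, 323 for WT 10 ppm, 488 for the WT trend and 5 for the TG trend. It gave 510 for the response difference of WT and KO, 612 for WT and TG and 288 for CD-1 and WT, and in air 1627 for KO and WT, 3976 for TG and WT, 540 for TG and KO and 1665 for CD-1 and WT. With 1 fit over all 80 arrays, which pools the spread of the strains, the counts were 119 for TG 120 ppm, 115 for CD-1 120 ppm, 17 for TG 40 ppm, 44 for CD-1 40 ppm, 222 for TG 10 ppm, 1 for CD-1 10 ppm, 96 for the TG trend, 155 for the CD-1 trend, 824 for WT and KO in response and 4 for TG and KO. Array weights gave 14 for TG 120 ppm, 4 for CD-1 120 ppm, 4 for TG 40 ppm, 7 for KO 10 ppm, 27 for the TG trend, and in response 1998 for WT and KO, 1706 for WT and TG, 7 for TG and KO and 913 for CD-1 and WT. Trended and robust variance gave 14 for TG 120 ppm, 2 for KO 10 ppm, 20 for the TG trend and 4 for the CD-1 trend. No filter on low genes gave 5 for TG 120 ppm and 4 for the CD-1 trend, and the mean of the gene's probe sets 15 and 4. Without the 4 arrays that stood apart the counts were 5 for TG 120 ppm, 5 for CD-1 120 ppm and 1 for TG 40 ppm. With the replicate block they were 4 for TG 120 ppm and 4 for CD-1 120 ppm; the numbers do not pair, and the block moved no other count. Median centring of each array gave 3 for TG 120 ppm, and in air 1560 for KO and WT and 4071 for TG and WT. Quantile normalization of the 80 arrays gave 1571, 4091 and, for CD-1 and WT in air, 3806. Both remove the shift between strains by construction.

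Leaving out each array in turn gave 2145 to 2501 genes for WT 120 ppm, 2432 to 2979 for WT 40 ppm, 919 to 1784 for WT 10 ppm and 2494 to 3191 for the WT trend. The ranges were 0 to 0 for KO 120 ppm, KO 40 ppm and the KO trend, and 0 to 2 for KO 10 ppm. They were 2 to 39 for TG 120 ppm, 0 to 1 for TG 40 ppm, 0 to 5 for TG 10 ppm and 3 to 28 for the TG trend, and 1 to 7 for CD-1 120 ppm, 1 to 1 for CD-1 40 ppm, 0 to 0 for CD-1 10 ppm and 1 to 22 for the CD-1 trend. In response they were 1090 to 1445 for WT and KO, 835 to 1458 for WT and TG, 0 to 12 for TG and KO and 326 to 621 for CD-1 and WT, and in air 8083 to 8257 for KO and WT, 8730 to 9153 for TG and WT, 2661 to 3223 for TG and KO and 5521 to 5778 for CD-1 and WT.

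Of 179 list calls, 11 were kept with an estimated correlation, 160 with 1 fit over all 80 arrays, 157 with no filter, 151 with median centring, 150 with quantile normalization, 179 with trended and robust variance, 154 with array weights, 163 with the mean of probe sets, 174 with the replicate block and 143 of 166 without the 4 arrays. Of 194 calls of named genes, 193, 187, 179, 180, 186, 191 and 189 were kept with 1 fit, no filter, centring, quantile normalization, trended variance, weights and the block, 185 of 188 with the mean of probe sets and 187 without the 4 arrays, and 2354 of 2510 calls held on leaving out each array. For a list the direction is that against all other genes and the value printed is its median. Reversed were the ciliated cell list of CD-1 120 ppm without CD-1 120 ppm replicate 1 (-0.157, range -0.157 to 0.178 over single arrays) and the heat shock list of CD-1 10 ppm without CD-1 10 ppm replicate 1 (-0.161, range -0.161 to 0.117). In air, median centring reversed the alveolar type 2 (0.142) and adipose tissue lists of KO and WT (0.124), the adipose tissue list of TG and WT (-0.09) and Cyp2f2 of CD-1 and WT (0.093). Quantile normalization reversed the adipose tissue list of KO and WT (0.118) and of TG and WT (-0.08) and the glucocorticoid response list of TG and WT (0.035). The adipose tissue median of TG and WT kept its negative sign (main value -0.605), and only its direction against other genes changed. Signal over background limits all of this: 11406 of 17097 genes lay above the level minimum of 4.28 in enough arrays to be tested.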

Other observations

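The genes in this part were chosen only after the result was seen. Of the 11 clock genes that passed in WT at 120 ppm, 10 had the other sign in CD-1 and 1 the same, and 0 of the 15 measured passed in CD-1. Of the 10, 4 are given here. In WT Dbp changed by -1.29 (adjusted p = 0.0111), Hlf by -0.86 (0.00456), Per3 by -0.86 (0.00589) and Arntl by 0.51 (0.0173). In CD-1 the values were 2.14 for Dbp (0.407), 1.18 for Hlf (0.266), 1.15 for Per3 and -1.72 for Arntl (0.066). The difference in response was -2.23 for Arntl (0.000404). In KO the values were 0.65 for Dbp and -0.49 for Arntl, and in TG -0.71 and 0.60. The lungs were taken on the morning after exposure, and the hour of each sample is not given in the sources used here.

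The inducible heat shock gene Hspa1b rose in WT by 2.27 at 120, 2.64 at 40 and 1.57 at 10 ppm. The mean of the cardiac muscle list per array had a standard deviation within groups that ran from 0.47 to 1.06 over the 16 groups. Probe sets without a gene name changed in 1254 of 6760 cases in WT at 40 ppm (539 up and 715 down) and in 438 at 10 ppm (257 up and 181 down), and 4 fell in KO at 10 ppm.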
